A study of Homo sapiens with 2 samples.

How the data were processed

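Messenger RNA of HEK-293T cells with a CIRTS-hADAR biosensor was sequenced without and with ABA, 1 library per condition and 1 biological replicate per the labels. Libraries were made with the KAPA mRNA HyperPrep kit. The submitters' processing notes name cutadapt, which trims adapters, HISAT2, a spliced aligner, and the hg19 genome build, with no versions. The program that counted bases at each position is not given in the sources used here.

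For each library the authors deposited 2 files of counts, the number of reads with A, C, G or T at each listed position, not normalised. Per the file headers, the plus-strand file lists A positions with their A-to-G counts, the minus-strand file lists T positions with their T-to-C counts, and a single base read cutoff of 5 was applied. The lowest depth found in the files is 6 reads. Minus-strand counts were read as their complement, so that T to C is A-to-G on the transcript. Positions without any mismatch are listed too, so rates over all covered A positions can be formed. Positions under the cutoff are missing from both numerator and denominator. Whether duplicate reads were removed is not given in the sources used here. No molecular identifiers are named, and 1 read covers several positions, so that counts at neighbouring positions are not independent and intervals are too narrow to that extent.

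The library without ABA had 4079392 listed positions with 51092343 base reads, and the ABA library had 3518802 positions with 45277712. Median depth was 10 reads in both, which allows a share to be set within wide limits alone. Of nuclear positions, 12.5% without ABA and 13.7% with ABA had at least 20 reads. Nuclear positions listed in both libraries numbered 2854489, of which 359090 had at least 20 reads in each. Nuclear means chromosomes 1 to 22 and X. Positions of chromosome Y, 2612 in number, were not used.

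The edited share of a position is G reads over A plus G reads, and the rate of a set of positions is the same with reads summed. Rates of A-to-C and A-to-T were formed the same way. The files list A positions of the transcript strand, so 2 background changes stood in for the 11 that had been planned. Intervals of shares are Clopper-Pearson, and those of ratios come from the exact conditional binomial, both at 95%. Those of differences in percentage points and of the ratio of 2 ratios are normal approximations at 95%. A fold against a count of 0 was taken against a floor of 3 reads. Positions with a share of at least 35% in either library are called variant-like.

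The site test, fixed before the data were examined, was a two-sided Fisher's exact test per nuclear position with at least 20 reads in both libraries, adjusted by Benjamini-Hochberg. A site was called raised or lowered at an adjusted p under 0.05 with a change of at least 10 percentage points. An edited site had at least 20 reads, at least 3 G reads and a share of at least 10%, and sites at 95% or more in both libraries were left out. Sites to be named were the 10 raised and 10 lowered sites with the largest change, at most 1 per gene. As none passed, the sites with the largest change by size alone were taken, 10 higher and all 6 lower, without the limit per gene. Other sites, of the lowest p or the highest share in the reporters and the chromosome 21 locus, were chosen after their values were seen.

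The reporter comparisons, the blocks, the firefly boundary at position 1700 and the chromosome 21 locus were also chosen after the data were seen. A block joins listed positions of 1 strand that are at most 100 nt apart, with variant-like positions left out and at least 200 reads in each library, and was tested by Fisher's exact test with Benjamini-Hochberg adjustment. The gap and the read minimum were set after trials with several gaps. The locus joins the plus-strand blocks within 50000 nt of the 3 raised blocks on chromosome 21, whatever their rate. The spread of ratios over the firefly bins was compared with 100000 simulated data sets that had 1 ratio in all bins. Reporter positions are counted as the files give them.

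Both tests were tested on simulated data with the observed depths and 200 changed sites or blocks, and made 0 false calls. The unchanged sites and blocks had 1 rate in both libraries and independent reads, unlike the observed data. Calls that only follow a general shift were therefore not tested for. Smaller block changes, of 5-fold and 10-fold, were not recovered. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 1. Alternatives to the coverage minimum, the share, the change, the test, the strands, the depth (thinned to the lower of both libraries) and the variant-like positions were run. A gene annotation of the hg19 build was not used here, so sites are given by coordinate, and the planned comparisons by gene list, by gene coverage and by markers of other cell types were not run.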

Results

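RNA from HEK-293T cells, a human embryonic kidney line, was compared without and with the small molecule ABA in cells that carried a CIRTS-hADAR biosensor. CIRTS is an engineered RNA-targeting system, and ADAR enzymes deaminate adenosine to inosine, which sequencing reads as G. A-to-G mismatches at transcript A positions were therefore counted, beside A-to-C and A-to-T mismatches at the same positions as background. Each condition had 1 library, so the difference between conditions has no replicate check. Intervals are at 95% and cover counting error alone. They are exact, except that those of differences in percentage points and of a ratio of ratios are normal approximations. The p-values, from two-sided Fisher's exact tests, compare the 2 libraries and not the conditions.

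Nuclear transcripts, from chromosomes 1 to 22 and X, carried more A-to-G mismatches in the ABA library. The rate was 0.0560% of reads (0.0554 to 0.0567) without ABA and 0.0953% (0.0944 to 0.0962) with ABA, a ratio of 1.70 (1.68 to 1.73). With the 1162 positions left out whose edited share reached 35% in either library, as an inherited variant would, the rates were 0.0386% and 0.0776%, a ratio of 2.01 (1.97 to 2.05). The A-to-C background at positions treated the same way was 0.00618% and 0.00746%, a ratio of 1.21 (1.15 to 1.27). A-to-T mismatches stood at 0.00396% and 0.00424%, a ratio of 1.07 (1.01 to 1.14). The A-to-G ratio was 1.73 on the plus strand and 1.67 on the minus strand.

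**Figure D1:**
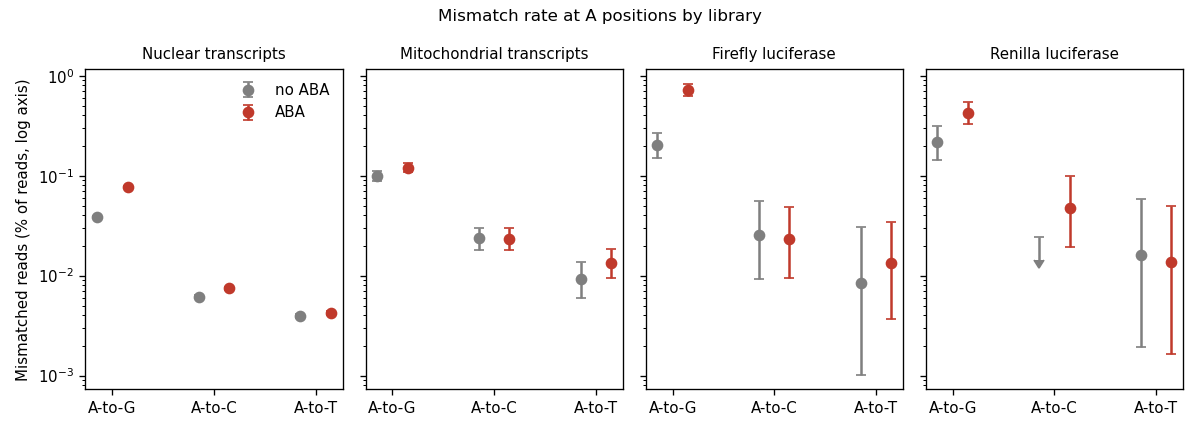
Mismatched reads as a percent of reads (log axis) by kind of change, in grey without ABA and in red with ABA, for nuclear and mitochondrial transcripts without variant-like positions and for the plus strand of both luciferase reporters. Points are the single library of each condition, bars are 95% exact intervals for counting error, and an arrow starts at the floor of 3 reads for a count of 0; the nuclear A-to-G rate was 0.0386% and 0.0776%.

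The A-to-G mismatches were spread over many positions. Of the nuclear positions listed in both libraries, variant-like positions left out, 0.553% had a G read without ABA and 0.978% with ABA. Positions with 1 G read held 89.9% of these reads without ABA and 81.2% with ABA. With variant-like positions kept these shares were 64.4% and 66.8%, so their direction depended on that choice. At this depth and these rates single G reads are common whatever their source, so the shares do not tell editing from error. The rate was higher with ABA on 23 of 23 chromosomes. Ratios ran from 1.47 (1.24 to 1.73) on chromosome 18 to 2.65 (2.31 to 3.05) on chromosome 21, with a median of 1.95. The chromosome 21 value rested on 1 locus, described last, without which it was 1.58 (1.34 to 1.88). Chromosome 19 had a ratio of 2.59 (2.41 to 2.78), and chromosome 13 had 1.59 (1.35 to 1.88).

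**Figure D2:**
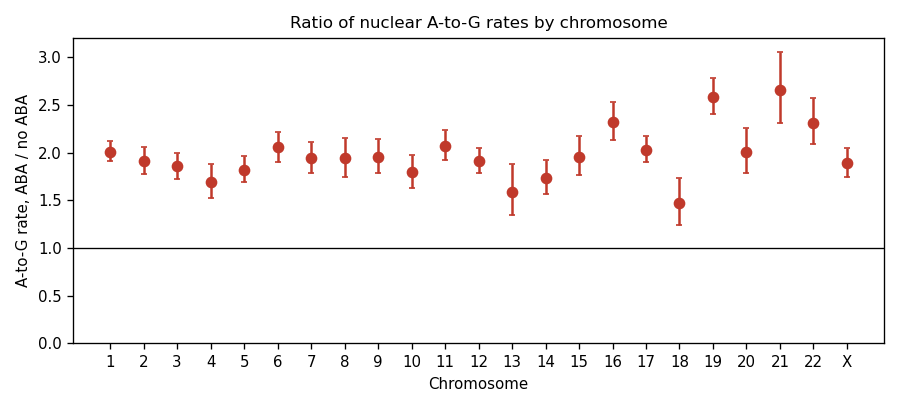
Ratio of the nuclear A-to-G rate with ABA to that without ABA (y axis, from 0) for each chromosome (x axis), with variant-like positions left out and 95% intervals for counting error. The line marks a ratio of 1, and the ratios on 23 of 23 chromosomes lie above it.

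Mitochondrial transcripts, which lie in another compartment than cytosolic and nuclear RNA, had a smaller ratio. Their A-to-G rate was 0.162% (0.147 to 0.178) without ABA and 0.175% (0.160 to 0.191) with ABA, a ratio of 1.08 (0.949 to 1.23). Without variant-like positions the rates were 0.0993% and 0.120%, a ratio of 1.21 (1.03 to 1.43), whose upper bound lay below the lower bound of the nuclear ratio of 2.01. In percentage points, from a higher baseline, the difference was 0.0211 (0.00369 to 0.0386) against a nuclear 0.0390 (0.0380 to 0.0400). These intervals overlap slightly, which does not test their difference. The mitochondrial A-to-C ratio was 0.987 (0.689 to 1.41). For A-to-T, without variant-like positions, it was 1.45 (0.855 to 2.51), from 25 and 38 reads.

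The files also listed positions of firefly and renilla luciferase, light-producing enzymes used as paired reporters, which the comparisons fixed before the data were examined did not foresee. Firefly RNA had the higher ratio. Its A-to-G rate was 0.203% (0.149 to 0.268) without ABA, 48 of 23695 reads, and 0.724% (0.631 to 0.826) with ABA, 217 of 29976 reads, a ratio of 3.57 (2.60 to 4.99; exact p = 3.24e-19). The firefly A-to-C rate was 0.0254% and 0.0235%. In renilla RNA the A-to-G rate was 0.217% (0.143 to 0.315) and 0.427% (0.328 to 0.546), from 27 and 63 reads, a ratio of 1.97 (1.24 to 3.22; exact p = 0.0028). Passing the threshold, though not the direction, rested on 1 position: without position 264 the counts were 27 and 51 reads, a ratio of 1.60 (0.983 to 2.65; exact p = 0.053). The renilla A-to-C background was not flat, with 0 reads of 12425 without ABA, where a floor of 3 reads is 0.0241%, and 7 of 14689 with ABA (exact p = 0.018). Both reporters were also deeper with ABA. Per 1000000 nuclear base reads at positions listed in both libraries, firefly had 576 without ABA and 748 with ABA, and renilla had 303 and 368. These ratios, 1.30 (1.28 to 1.32) and 1.22 (1.19 to 1.24), lay above 91.1% and 84.4% of nuclear blocks of neighbouring positions. Those blocks held a median of 36 positions, against 439 for firefly and 241 for renilla, so counting error widens their spread. The ranks therefore do not show how usual such a difference is.

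Within firefly RNA the 3' end had the highest A-to-G rate with ABA, while without ABA the 100-nt bin from position 1200 was highest, at 0.643% (0.309 to 1.18). From position 1700 to the last listed position, 1866, the rate was 0.359% (0.210 to 0.575) without ABA and 1.85% (1.55 to 2.20) with ABA, a ratio of 5.16 (3.10 to 9.13). Before position 1700 it was 0.163% and 0.389%, a ratio of 2.38 (1.57 to 3.71). This boundary was chosen after the values were seen. Over all 100-nt bins of the reporter that held a G read, 18 in number, a spread of the ratios as large arose from counting error in a share of 0.117 of simulated data sets. This test of all bins together thus did not detect a difference between them. Its power for a larger ratio at the end alone was not measured. The highest single share was at firefly position 1296, with 4 of 46 reads (8.70%, 2.42 to 20.8) without ABA and 16 of 74 (21.6%, 12.9 to 32.7) with ABA (exact p = 0.080). Position 1828 had 1.54% and 7.47% (exact p = 0.0027). Renilla position 264 had 0 of 45 reads without ABA and 12 of 70 (17.1%, 9.18 to 28.0) with ABA (exact p = 0.0031). No reporter position passed Benjamini-Hochberg adjustment. A-to-G shares were higher with ABA at 83 and lower at 22 of 426 firefly positions with at least 20 reads in both libraries, and higher at 33 and lower at 20 of 227 renilla positions.

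**Figure D3:**
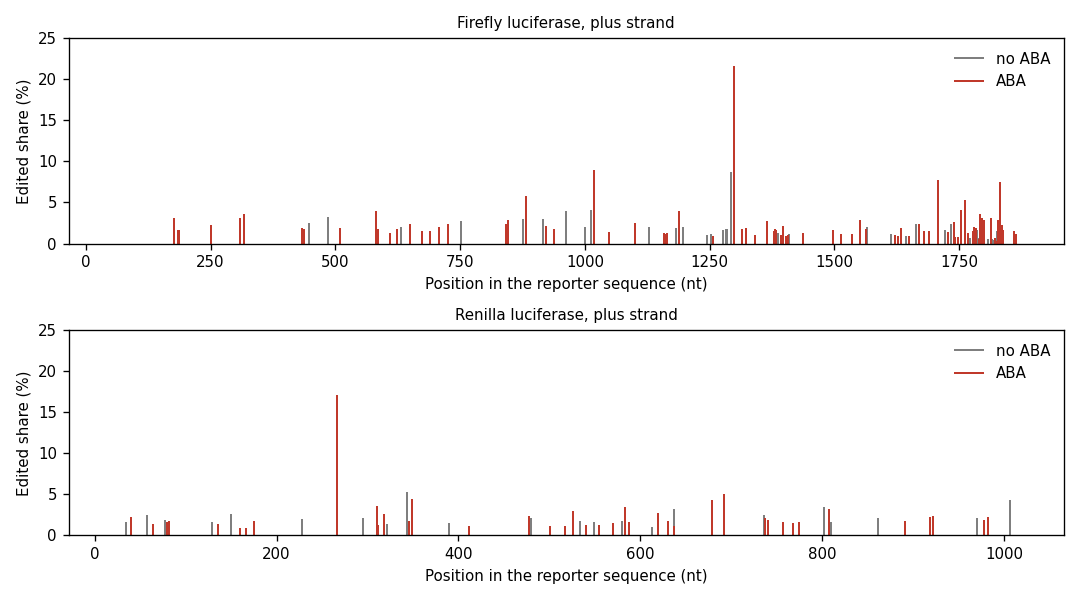
Share of reads with G (y axis, percent) at each A position of firefly luciferase (top) and renilla luciferase (bottom) with at least 20 reads, along the reporter sequence (x axis, nt), in grey without ABA and in red with ABA, each drawn 3 nt to either side of its position. The highest shares with ABA are 21.6% at firefly position 1296 and 17.1% at renilla position 264.

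Edited nuclear sites were more numerous in the ABA library. A site was called edited in a library with at least 20 reads, at least 3 G reads and a share of at least 10%, unless the share reached 95% in both libraries. There were 100 such sites among 507873 covered positions without ABA, 1.97 per 10000 (1.60 to 2.39), and 203 among 479349 with ABA, 4.23 per 10000 (3.67 to 4.86). The same rule gave 16 and 21 sites for A-to-C, and 8 and 6 for A-to-T. Among the 359090 positions with at least 20 reads in both libraries, 58 sites were edited in both, 7 without ABA alone and 96 with ABA alone. Of the 58, 26 had a share of 35% or more in both libraries, as an inherited variant would. With sites at that level in both left out, the counts of 100 and 203 became 62 and 167. The contrast depended on the limits set. At a share of at least 5% there were 124 sites without ABA and 413 with ABA, and at 20% there were 74 and 75. With a coverage minimum of 10 there were 374 and 428, while a coverage minimum of 50 gave 11 and 41.

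No single nuclear site passed the test between libraries. Of the 359090 positions, 0 rose and 0 fell at an adjusted p under 0.05 with a change of at least 10 percentage points. Size alone gave 84 sites higher and 6 lower with ABA, against 2 higher and 0 lower for A-to-C and 1 higher and 0 lower for A-to-T. An unadjusted exact p under 0.05 gave 63 sites higher and 2 lower. The depth limits this test: on simulated data it recovered 1.5% of sites raised by 20 percentage points, 27.5% at 40 points and 81.5% at 60 points. The balance by size also depended on the limits: a coverage minimum of 10 gave 968 higher and 324 lower, a change of at least 5 points 824 and 209, and a coverage minimum of 50 gave 15 and 1. The 84 sites lay on 21 chromosomes, and 49 of them had 0 G reads without ABA. Their pooled share was 6.47% without ABA and 19.95% with ABA, a contrast that their selection by size enlarges.

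Since no site passed, the sites named are those with the largest changes by size alone, given by hg19 coordinate. The largest was on chromosome 9 at 135895653 (plus strand), with 1 of 22 reads (4.55%, 0.115 to 22.8) without ABA and 7 of 24 (29.2%, 12.6 to 51.1) with ABA. Next came chromosome 21 at 46640856 (plus), with 16 of 67 reads (23.9%, 14.3 to 35.9) and 51 of 113 (45.1%, 35.8 to 54.8). Chromosome 2 at 10930903 (minus) had 21.6% and 42.1%. From 0 reads without ABA, chromosome 1 at 212792997 (plus) had 5 of 25 reads with ABA, chromosome 15 at 40605280 (minus) 19.0% and chromosome 7 at 22550912 (minus) 17.6%. Shares of 34.8% or more in both libraries were found on chromosome 1 at 220321023 (plus), 40.5% and 59.5%, chromosome 5 at 224633 (plus), 44.8% and 63.3%, and chromosome 15 at 80137560 (minus), 34.8% and 52.2%. The tenth was chromosome 21 at 46602538 (plus), with 9.52% and 26.8%.

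The 6 lower sites had smaller changes than the 10 higher sites named. Chromosome 15 at 67494494 (minus) had 43.5% without ABA and 27.3% with ABA. Chromosome 2 had 35.1% and 22.2% at 135893372 (plus) and 38.6% and 26.5% at 65497682 (plus). Chromosome 3 at 49397323 (minus) had 8 of 63 reads (12.7%) without ABA and 0 of 57 with ABA (exact p = 0.0066). The other 2, chromosome 12 at 31404996 and chromosome 5 at 137854471 (both minus), had 2 of 20 reads without ABA and 0 with ABA.

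The lowest unadjusted p-values belonged to deeper sites, chosen after their values were seen. Chromosome 11 at 62338570 (minus) had 2 of 100 reads (0.243% to 7.04%) without ABA and 15 of 80 (18.8%, 10.9 to 29.0) with ABA (exact p = 0.00015, adjusted p = 1). A second site on that chromosome, at 62339100 (minus), had 0 of 57 and 12 of 73 reads (16.4%, 8.79 to 27.0). Chromosome 19 at 3980934 (minus) had 0 of 204 and 12 of 201 reads (5.97%, 3.12 to 10.2). Chromosome 6 at 74228485 (minus) had 2.73% and 17.4%, and chromosome 12 at 6647015 (plus) had 0 of 76 and 12 of 103 reads (11.7%, 6.17 to 19.5).

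Reads were then pooled over blocks of neighbouring positions, a step added after the site test had been seen. Of 43870 blocks with at least 200 reads in both libraries, 6 had a higher A-to-G rate with ABA at an adjusted exact p under 0.05 and 0 had a lower one. The test is against equal rates and not against the nuclear ratio of 2.01, so a deep block can pass by following the general shift. Before any test, 11798 blocks had a higher rate with ABA and 5665 a lower one. An unadjusted exact p under 0.05 was reached by 239 higher and 10 lower blocks. On simulated data, with blocks of all depths and 1 common starting rate, the test recovered 0 of 200 blocks raised 10-fold, 1% at 20-fold, 35.5% at 50-fold and 76% at 100-fold. Smaller changes passed in the observed data in blocks of greater depth or higher starting rate, down to 3.32-fold.

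Of the 6 raised blocks, 3 lay within 1 locus of chromosome 21. The other 3 were as follows. Chromosome 15 from 89173296 to 89175501 (plus) went from 0 of 6858 reads to 26 of 6050 (0.430%, 0.281 to 0.629), at least 9.82-fold higher against a floor of 3 reads, counting error of the 26 reads aside (adjusted p = 0.00012 from the exact test). Chromosome 12 from 125396208 to 125398311 (minus) rose from 0.0832% (0.0533 to 0.124) to 0.276% (0.219 to 0.344). Chromosome 1 from 45243291 to 45243457 (plus) rose from 0.196% (0.105 to 0.336) to 0.727% (0.533 to 0.969), with an adjusted p of 0.041 from the exact test. Its ratio was 3.70 (1.97 to 7.47), and that of the chromosome 12 block was 3.32 (2.08 to 5.48). The lower bound for chromosome 1 lies below the nuclear ratio of 2.01, and that for chromosome 12 barely above it. With the position of most edited reads left out of each block, 3 of the 6 were still raised, 1 of them in the chromosome 21 locus.

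The chromosome 21 locus, from 46596515 to 46642104 (plus), held 8 blocks with 302 positions, and the rate was higher with ABA in 8 of 8. Pooled over the blocks, its A-to-G rate was 0.261% (0.194 to 0.343) without ABA and 1.23% (1.11 to 1.36) with ABA, a ratio of 4.70 (3.50 to 6.43). As the locus was drawn around its 3 raised blocks, this ratio is enlarged by their selection. The 5 other blocks had 0.361% (0.256 to 0.495) and 1.30% (1.13 to 1.49), a ratio of 3.61 (2.54 to 5.24), and were higher in 5 of 5. The construct carries a human ADAR sequence, whose reads would align to the gene it came from. Which gene lies here was not determined, so the locus reads, its sites and its blocks need not stem from the cells' own transcripts. Over all listed nuclear positions, variant-like ones kept, the ratio was 1.70 with the locus and 1.69 without it. With variant-like positions put back, 304 positions in all, the locus had 0.467% and 1.57%, a ratio of 3.37 (2.69 to 4.25). A-to-C and A-to-T together stood at 0.0255% and 0.0430% over these 304 positions. Its 3 raised blocks rose from 0.0769% to 1.16% at 46641943 to 46642104, from 0.282% to 1.69% at 46624474 to 46624648, and from 0.101% to 0.757% at 46604836 to 46605004. Of 290 positions with at least 20 reads in both libraries, 102 had a higher share with ABA and 11 a lower one. Position 46640815 had 26.9% and 39.7%, besides the 2 sites named above. Read depth at the locus, relative to all nuclear reads, was 1.60 times as high with ABA (1.57 to 1.63), above 99.0% of all blocks.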

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

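All tests in this part were chosen after the result they bear on was seen. The minus strand of renilla luciferase, which no comparison used, carried A-to-G mismatches. Their rate was 0.352% (0.142 to 0.725) with ABA, 7 of 1986 reads, above the 0.0540% without ABA, 1 of 1853 reads. The difference was not past the threshold (exact p = 0.071), and no explanation was tested.

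The higher nuclear A-to-G rate with ABA was set against more base-calling error, an artefact acting on all RNA, and more transfected RNA. A-to-C and A-to-T mismatches together had a ratio of 1.15 (1.11 to 1.2), against 2.01 for A-to-G. This argues against base-calling error that raises all kinds of change by the same ratio as the whole cause. An error of A-to-G alone would not show in the other changes and stays open. Mitochondrial transcripts had an A-to-G ratio of 1.21 (1.03 to 1.43), which argues against an artefact that multiplies the rate of all RNA. Their rise of 0.0211 percentage points (0.00369 to 0.0386) overlaps the nuclear 0.0390 (0.0380 to 0.0400), but overlap does not test the difference. Mitochondrial positions were also deeper, with medians of 46 reads without ABA and 53 with ABA. The nuclear rise was 0.0272 points from 6 to under 10 reads, 0.0293 from 10 to under 20, 0.0425 from 20 to under 50 and 0.105 from 50. From 20 reads up it lay above the mitochondrial upper bound. Whether an artefact adds the same share to all RNA was therefore not settled by this comparison. Depth of both reporters was 1.27 times as high with ABA (1.25 to 1.29), below the 95th percentile of all blocks at 1.38. That percentile includes the counting error of blocks with fewer positions. The chromosome 21 locus, whose reads may stem from the construct, was 1.60 times as deep (1.57 to 1.63). More transfected RNA may add to the rate and stays open, as how the rate scales with the construct was not measured. Deamination set off by ABA stays open as well, and with 1 library per condition it cannot be told apart from other differences between the cultures.

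For the high A-to-G rate with ABA at the 3' end of firefly RNA, sequencing or alignment error and a ratio common to the whole reporter were weighed. A-to-C and A-to-T mismatches in this window were 0.0446% (0.00920 to 0.130) with ABA, against 1.85% for A-to-G. This argues against such error where it affects all kinds of change alike, and not against an error of A-to-G alone. The ratio of the window ratio to that in the rest was 2.17 (1.13 to 4.15), but the window had been picked by its values. Over all bins, 1 common ratio gave a spread as large in a share of 0.117 of simulated data sets. That test looks at all bins together, and its power for the end alone was not measured. A window specific response and a common ratio on a higher baseline were therefore not told apart.

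The chromosome 21 locus was set against alignment error, greater depth and reads from transfected RNA. A-to-C and A-to-T mismatches were 0.0430% (0.0229 to 0.0735) with ABA, against 1.57% for A-to-G. This argues against alignment error that affects all kinds of change alike, and not against an error of A-to-G alone. The 5 locus blocks that had not been called had an A-to-G ratio of 3.61 (2.54 to 5.24), above the nuclear 2.01, and 2 of the 3 called blocks still passed with both libraries thinned to the lower depth of each position, which argues against depth as the whole cause. Depth of the locus rose 1.60 times, more than the reporters and above the 95th percentile of all blocks at 1.38, so reads from transfected RNA that align to the locus, as the construct's human ADAR sequence would to its own gene, are a candidate source of the signal. A change in the cells' own transcript stays open and was not tested.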

How the results depend on the processing

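Alternatives for the reporters and blocks, and those named here as added, were chosen after the data were seen. The nuclear A-to-G ratio of 1.70 stayed above 1 under the 9 alternatives run and left its counting interval in 6: 1.77 at positions with at least 50 reads in both libraries, 1.62 as a mean of shares, 2.01 without variant-like positions, 1.73 and 1.67 on the plus and minus strands, and, as an added alternative, 1.67 without the 100 positions with the largest gain. The mitochondrial ratio was 1.27 at positions with at least 50 reads. The counts of 0 raised and 0 lowered sites became 84 and 6 by size alone, which drops the whole test, and 63 and 2 at an unadjusted p under 0.05, an added alternative that drops both the adjustment and the size limit; under the other alternatives run they stayed at 0. Edited sites without ABA numbered 374 and 11 at coverage minimums of 10 and 50, 62 without sites at 35% or more in both libraries, 65 where covered in both and 64 after thinning. With ABA they numbered 428 and 41 at those coverage minimums, and 413 and 75 at shares of at least 5% and 20%, against 124 and 74 without ABA. The firefly ratio was 2.38 without the window from position 1700 and 5.16 in it, and the renilla ratio was 1.60 without position 264, no longer past the threshold (exact p = 0.053). Raised blocks numbered 10 with a gap of 500 nt and 3 without the position with the most edited reads in each block. Other causes of these shifts were not tested. At single positions, 81 of 82 added alternatives stayed within a band around the change as wide as the interval of the ABA share. This band is not an interval of the change. The alternatives that took the share of all reads nearly repeat the edited share, so this count says little about robustness. Renilla position 805 changed sign after thinning, from -0.170 to 0.0605 percentage points, a shift well within counting error. The gene list and gene coverage alternatives were not run. Depth limits the site test, which on simulated data recovered 1.5% of sites raised by 20 percentage points.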

Other observations

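The test of the neighbouring base on the 5' side was chosen before its result was seen, and the values for the 3' side and for depth were not planned. ADAR enzymes are known to prefer an A or U on the 5' side of the edited A. The neighbour could be read from the files where both strands were listed around a position. The A-to-G rate after an A or T was 0.122% without ABA and 0.251% with ABA at 6657 nuclear positions, a rise of 0.129 percentage points. After a C or G it was 0.117% and 0.185% at 11112 positions, a rise of 0.0671 points. The difference between the rises was 0.0617 points (0.0358 to 0.0875), which is consistent with deamination by an ADAR enzyme, as a hypothesis. On the 3' side the rise was 0.163 points before a C or G, 0.0742 before a T and 0.0270 before an A. These positions are few and lie where both strands are transcribed or aligned, so the values need not hold for all transcripts.

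Both A-to-G rates were higher at deeper positions, among nuclear positions listed in both libraries with A-to-G variant-like positions left out. From 6 to under 10 reads the rates were 0.0243% and 0.0516% (ratio 2.12), from 10 to under 20 reads 0.0313% and 0.0605% (1.94), from 20 to under 50 reads 0.05003% and 0.0925% (1.85), and from 50 reads 0.122% and 0.227% (1.86). The A-to-C rate without ABA also went from 0.00540% in the shallowest to 0.0208% in the deepest of these classes. Positions variant-like for A-to-C were kept here, unlike in the background rates given first, and may add to these values.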
